A study of Mus musculus with 8 samples.

How the data were processed

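Total RNA of whole kidneys, in 4 control samples and 4 samples of tacrolimus-treated mice, was labelled with Cy3 from 0.2 ug each (RIN 9 for all 8, per the labels) and hybridised to 1-colour Agilent mouse arrays of 62976 features. Intensities were read from the scanner images with Agilent Feature Extraction 10.7.3.1, per the file headers, which gives a raw mean and median intensity per spot, a local background, and a processed intensity from which the background has been subtracted with spatial detrending. Each scanner file holds 1 array and is not normalized between arrays. The deposited value table holds log2 values of all features: set against the scanner columns, each of its columns equals, to within 5e-09, the log2 of the quantile-normalized raw median intensity with no background subtracted, genes are not centred, and direction is not at issue with 1 colour. Its column medians were 6.32, 6.31, 6.30 and 6.31 for control replicates 1 to 4 and 6.31, 6.31, 6.30 and 6.31 for tacrolimus replicates 1 to 4. The submitters' processing notes name limma, and its settings are not given in the sources used here. Without background subtraction, differences of dim probes are compressed in that table.

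The values reported were computed from the scanner files: log2 of the processed intensity minus the 75th percentile of the same array over its 59305 non-control spots. The 3671 control features and spots marked as outliers by the scanner software (147 to 194 per array) were left out, and the spots of a probe, up to 10, were averaged, giving 55681 probes, of which 32 with no value on some array were left out. A probe was tested if it was well above background on at least 4 of the 8 arrays, whatever their group, which kept 36493 probes. A gene with several such probes was represented by the one with the highest mean, and 25127 genes and unnamed transcripts were tested, 15765 of them under a gene symbol. Current symbols were taken through the accession from an NCBI RefSeq table of the GRCm38.p6 assembly, which matched 28026 probes and renamed 1651, and the name in the files was kept otherwise. Probe positions are those of the array annotation on mm9. Different probes of 1 gene can disagree, and further probes are given for some of the named genes.

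Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes tested, called at an adjusted p under 0.05), with no further terms. Tested on simulated arrays with the real genes' means and spreads for this comparison, 25127 genes with 100 changed by 1 and 100 by 2 log2 units, the fit recovered 72% and 85% of them, with 9 of its 166 calls on unchanged genes. The simulated genes varied independently and had no signal floor, so that these rates need not hold for the real arrays. Where a probe was not well above background on any array of 1 group, the difference is given as a bound: the mean of the other group against the mean, over the dim group's arrays, of the higher of the lowest signal well above background on that array and the probe's own signal. The design, the 37 gene lists (1008 genes, of which 942 were tested and 7 are not named on the array), the 16 advance genes and the naming rule were fixed before the data were examined. The rule names, among called genes with a symbol whose groups do not overlap, the 12 largest fitted increases and the 12 largest fitted decreases (5 qualified for the latter), in each described list up to 4 members with the lowest unadjusted p, and the advance genes whatever their values. Clone, model and region identifiers are counted and take no place. Some genes that the rule names are not reported here, and counts include them.

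Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01 and adjusted over the lists, and with an estimated correlation and fry beside it. In simulated arrays whose genes varied independently and where 3 lists were shifted by 0.5 log2 units, camera called those 3 and no other list. In the real data the estimated correlation reached 0.593 for interferon-stimulated genes and 0.729 for oxidative phosphorylation. The simulation therefore does not test false calls from correlated genes. Fry tests whether a list's genes move on balance one way and compares them with no other genes. Single values were also tested with an exact permutation test over the 70 assignments of the 8 arrays.

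Alternatives tried were quantile or median normalization, normexp background correction (offset 50) on the mean intensity, the deposited table, no filter or a filter on all 8 arrays, the mean of a gene's probes, an intensity trend with robust estimation, array weights, the replicate number as a block and leaving out each array. The 8 arrays lay on 1 slide and were scanned in 1 session, so that neither could be tested as a batch. Their values correlated between 0.982 and 0.993 across genes, and no array repeats another.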

Results

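Kidney RNA of CD-1 mice, an outbred laboratory stock, was measured on 1-colour Agilent mouse gene expression arrays. Tacrolimus, a calcineurin inhibitor used to prevent rejection of transplanted organs and known for its toxicity to the kidney, was given at 1 mg/kg/day for 28 days to the mice of 1 group, and physiological serum to the mice of the other. Each group had 4 arrays, and the labels number them as replicates without naming the animals, so that the p-values measure the spread between these samples. Between 64.0% and 69.8% of the non-control spots of an array were well above background, no spot was saturated, and the 75th percentile of the processed signal lay between 674 and 1061 intensity units. With 4 arrays per group, the number of arrays limits the precision of every value. All 8 arrays were on 1 slide, with the control arrays in row 1 and the tacrolimus arrays in row 2, so that the row on the slide and the treatment cannot be told apart. The local background was 23.3 to 23.4 intensity units on the control arrays and 20.3 to 21.8 on the tacrolimus arrays. Levels are log2 signals relative to the 75th percentile of the same array, and differences are tacrolimus minus control. The comparison addresses which transcripts of the kidney differ under a drug with known renal toxicity.

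Under tacrolimus the kidneys held more RNA of chemokines, of a cytokine-induced ubiquitin-like protein, and of an epithelial keratin. Ubd, a ubiquitin-like protein induced by interferon-gamma and tumour necrosis factor, rose from -3.17 ± 1.10 to 1.71 ± 1.09 (SD, n = 4 per group), a 29.3-fold difference. The chemokine Ccl8 rose 18.4-fold, from -4.64 ± 1.02 to -0.44 ± 0.59, and Ccl2, which attracts monocytes, rose 8.70-fold, from -1.42 ± 0.80 to 1.70 ± 0.70. Krt20, a keratin of differentiated epithelium that injured tubules also express, rose from -5.33 ± 1.15 to -0.35 ± 0.72, with 3 of the 4 control arrays well above background. Of the 25127 genes and unnamed transcripts tested, 57 differed at an adjusted p under 0.05 (limma), 47 of them higher and 10 lower. At an unadjusted p under 0.05 there were 3885, of which 1769 were higher and 2116 lower, where chance gives 1256 on average. Genes vary together, so that a single split of the arrays can lie far from that average. Of the 35 splits into 4 and 4, the real one gave the most, and the others gave from 460 to 3053. The 4 tacrolimus arrays lay entirely above or entirely below the 4 control arrays in all 57, which their selection by a low p made likely. They did so in 10.1% of all tested genes, where chance gives 2.86% on average, and a single split can lie far from this average too. The first principal component held 29.2% of the variance and placed the control arrays between -48.8 and -20.1 and the tacrolimus arrays between 13.1 and 41.3.

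Snph encodes syntaphilin, a protein that anchors mitochondria to microtubules in axons. It was not well above background on any control array, so that its difference is given as a bound, and reached -2.60 ± 0.19 (SD, n = 4) under tacrolimus, at least 12.2-fold higher (adjusted p = 0.000874, limma). In all, 11 of the 47 genes that rose were not well above background on any control array. Serpina3n, a serine protease inhibitor of the acute phase, was at least 4.97-fold higher, and H2-DMb2, a chain of the complex that loads peptides onto class II molecules, at least 5.22-fold. Clic6, a chloride intracellular channel protein, was at least 5.16-fold higher and the cannabinoid receptor gene Cnr1 at least 5.08-fold. Arhgap36, at least 3.30-fold higher, and the olfactory receptor gene Olfr1270, at least 2.92-fold higher, were also among the 12 largest fitted increases, whose adjusted p lay between 0.000874 and 0.0470. A further probe of Cnr1 was not well above background on any array and differed by 0.50 (unadjusted p = 0.109, limma). With normexp and the 75th percentile, which adds an offset to the signal, all 7 of these genes differed by less than their bounds. Snph, Serpina3n and H2-DMb2 then differed by 1.77, 0.88 and 1.06 and were called, and Clic6, Cnr1, Arhgap36 and Olfr1270 differed by 1.05, 0.96, 0.70 and 0.62 and were not called (adjusted p = 0.0559, 0.0651, 0.103 and 0.0781, within a range over settings of 0.00731 to 0.266). With no filter on dim probes Ubd, H2-DMb2 and Ccl2 were not called (adjusted p = 0.0668, 0.0544 and 0.0776, within a range over settings of 0.00230 to 0.441). The array annotation in the files gives positions on the mm9 assembly. The probe of Snph lies on chromosome 2 from 151416298 to 151416357 and that of Krt20 on chromosome 11 from 99289776 to 99289835. That of Ubd lies on chromosome 17 from 37332688 to 37332747, that of Ccl8 on chromosome 11 from 81930108 to 81930167, and that of Ccl2 on chromosome 11 from 81850650 to 81850709. Exon annotation of that assembly was not used here, and the probes were not checked for cross-hybridisation with other transcripts.

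As fitted, the 5 named decreases were smaller than the named increases, although the size of Stc1 and of several increases is only bounded. Stc1, encoding the glycoprotein hormone stanniocalcin 1, fell from -5.27 ± 0.37 (SD, n = 4) to below detection on every tacrolimus array, at least 1.81-fold lower. Its probe is placed on chromosome 14 from 69649656 to 69650303. Hnf4g, a nuclear receptor of epithelial cells, fell by 0.62 ± 0.09 (SE), the zinc finger gene Zfp459 fell by 0.92 ± 0.12, Tbc1d20, a GTPase-activating protein for Rab1, fell by 0.69 ± 0.10, and the tachykinin receptor gene Tacr2 fell by 0.52 ± 0.08 on the log2 scale. Stc1 differed by -0.33 with normexp and the 75th percentile (adjusted p = 0.328, the highest over the settings, the lowest being 0.0206), and with no filter on dim probes none of the 5 was called (limma, adjusted p from 0.0551 to 0.0888). None of the 5 was called with the replicate number as a block either (limma, adjusted p from 0.0524 to 0.0869). A further probe of Tacr2 was not well above background on any array. The number of genes called varied with the array left out: it was 7 without control replicate 2, 13 without control replicate 3 or 4, 18 without tacrolimus replicate 1, 22 without tacrolimus replicate 2 and 33 without tacrolimus replicate 3. Of the 17 named genes 3, 4, 5, 7, 8 and 7 stayed called without these arrays in turn, and 11 without tacrolimus replicate 4. Without control replicate 1 the number was 56, and without tacrolimus replicate 4 it was 46. All 57 genes kept their direction in each of these fits, which have fewer arrays. Other settings moved the number between 32, with no filter on dim probes, and 309, with array weights, and under normexp with quantile normalization 68.7% of the calls were higher against 82.5% in the values above. With the level of adipocyte markers on each array as a covariate, a setting chosen after seeing the data, 0 genes were called (limma), with 2186 under an unadjusted p of 0.05 and a smallest adjusted p of 0.0543. Without control replicate 2 and tacrolimus replicate 4 together, also chosen after seeing the data, 8 were called.

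**Figure D1:**
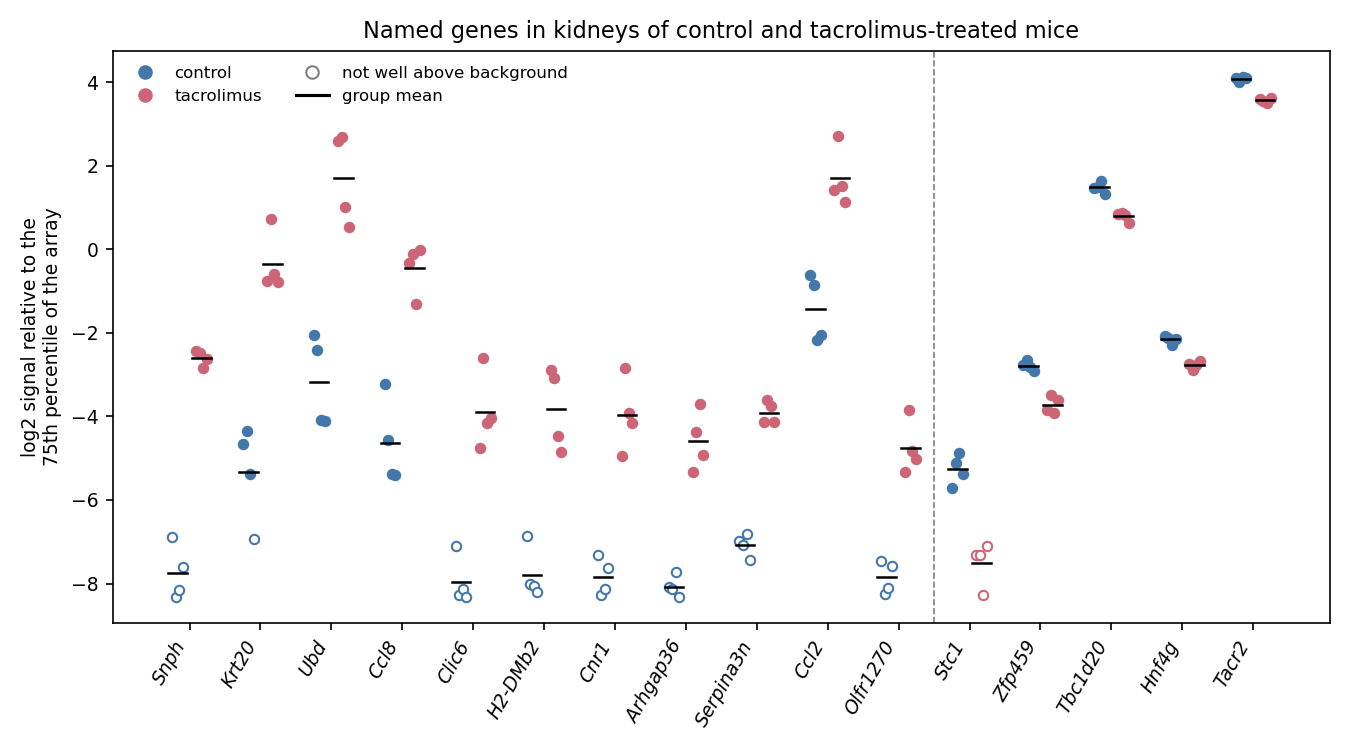
The vertical axis gives the log2 signal relative to the 75th percentile of the array for 11 of the 12 called genes with the largest fitted increase (left of the dashed line) and the 5 named decreases (right), with 1 point per array, black lines for the group means and open points for arrays where the probe was not well above background. For Snph the control mean is -7.74 and the tacrolimus mean -2.60, and in each gene shown the groups do not overlap.

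Genes of the extracellular matrix were higher under tacrolimus. Of the 48 measured members of the list for extracellular matrix and fibrosis, 30 rose and none fell when adjusted over the list alone, 18 did not pass, and 1 passed over all genes tested. That one was Col1a2, a chain of type I collagen, which rose by 1.14 ± 0.16 (SE). Ltbp2, a microfibril-associated protein, rose by 2.66 ± 0.41 and the fibril-associated collagen Col14a1 by 1.04 ± 0.16. The matrix metalloproteinase Mmp7 rose 3.96-fold, with 2 of the 4 control arrays well above background for Mmp7. The list's score, its members' mean relative to the control mean, was 0.68 ± 0.19 (SD, n = 4) on the tacrolimus arrays, against an SD of 0.07 on the control arrays. Camera, limma's competitive set test, gave an adjusted p of 2.85e-25 with its preset correlation, and adjusted p = 0.123 with an estimated correlation.

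Genes of proliferating cells moved the same way. In the cell cycle list 27 of 36 members rose, 9 did not pass and none fell when adjusted over the list alone, and 2 passed over all genes. Cdca3, a trigger of mitotic entry, rose by 0.91 ± 0.11 (SE), Birc5, encoding survivin of the chromosomal passenger complex, by 1.25 ± 0.18, and the cyclins Ccnb2 and Ccna2 by 1.19 ± 0.19 and 0.91 ± 0.14. Both further probes of Birc5 moved the same way, by 1.42 and 1.36. Camera gave an adjusted p of 1.31e-23, and adjusted p = 0.214 with an estimated correlation.

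Markers of myeloid cells and inflammatory mediators were higher as well. Of the 27 measured macrophage and dendritic cell markers, 22 rose, 1 fell and 4 did not pass when adjusted over the list alone, and none passed over all genes (limma), where 23 were higher and 1 was lower at an unadjusted p under 0.05. The mannose receptor Mrc1 rose by 1.88 ± 0.31 (SE), the lysozyme Lyz1 by 1.53 ± 0.26 and C1qa, a chain of complement C1q made by macrophages, by 1.32 ± 0.24. Itgam, the integrin chain CD11b, fell by 0.44 ± 0.08 at its brightest probe, while its other probes differed by 0.13 and -0.34 (unadjusted p = 0.269 and 0.134). In the list of inflammatory cytokines, chemokines and NF-kB targets 19 of 36 members rose, 17 did not pass and none fell adjusted over the list alone, and 3 passed over all genes. These 3 were Ccl8, Ccl2 and the adhesion molecule Vcam1, which rose by 2.39 ± 0.31, and Birc3, an inhibitor of apoptosis downstream of NF-kB, rose by 0.79 ± 0.12 in the list. The scores on the tacrolimus arrays were 1.15 ± 0.41 for the myeloid list and 0.92 ± 0.31 for the inflammatory list (SD, n = 4). Camera gave adjusted p values of 9.50e-19 and 2.36e-15, and adjusted p = 0.214 for both with an estimated correlation.

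Interferon-stimulated genes, tubular injury genes and complement genes completed the 7 lists with the lowest p. Of 38 interferon-stimulated genes, 21 rose, 17 did not pass and none fell adjusted over the list alone, and 1 passed over all genes. Oasl1, a 2'-5'-oligoadenylate synthetase-like protein, rose by 1.18 ± 0.17 (SE), Oas1a by 0.84 ± 0.18, the antiviral GTPase Mx1 by 1.69 ± 0.37 and the guanylate-binding protein Gbp6 by 1.19 ± 0.28. In the tubular injury and repair list 15 of 33 rose, 18 did not pass and none fell adjusted over the list alone, and 2, Krt20 and Vcam1, passed over all genes. Complement component C3, counted in this list and in the next, rose by 2.61 ± 0.41 and by 1.70 at a further probe, and Areg, a ligand of the EGF receptor, was not well above background on any control array and was at least 2.26-fold higher. Of 39 complement and coagulation genes 18 rose, 1 fell and 20 did not pass adjusted over the list alone, and none passed over all genes (limma), with 18 higher and 2 lower at an unadjusted p under 0.05. C1s1, a protease of the classical pathway, rose by 0.87 ± 0.13, with a further probe that was dim on every array at 0.21, and Proc, encoding protein C, was the member that fell, by 0.38 ± 0.08. Camera gave adjusted p values of 4.49e-21, 1.47e-11 and 5.37e-09 for the interferon, injury and complement lists, and adjusted p = 0.294, 0.214 and 0.123 with an estimated correlation.

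Markers of fat tissue also differed between the arrays. The adipose score was 1.46, 0.95, 1.03 and 3.51 on tacrolimus replicates 1 to 4, and -0.26, 1.02, -0.38 and -0.38 on control replicates 1 to 4, an exact two-sided permutation p of 0.0571 (adjusted over the 37 lists, 0.192). Tacrolimus replicate 4, the highest in this score, had the lowest scores of the 4 tacrolimus arrays for macrophages (0.72), inflammation (0.61), interferon-stimulated genes (0.30) and the cell cycle (0.56). It lay above tacrolimus replicate 3 for the extracellular matrix (0.613 against 0.498), tubular injury (0.854 against 0.526) and complement (0.669 against 0.407). Control replicate 2, the control highest in the adipose score, was also the highest control for macrophages (0.385), inflammation (0.279) and interferon-stimulated genes (0.103). It was also highest for tubular injury (0.167) and complement (0.128), and control replicate 1 for the extracellular matrix and the cell cycle. Of 13 measured adipose markers 5 rose and 8 did not pass adjusted over the list alone, and none passed over all genes (limma), with 6 under an unadjusted p of 0.05. Adipoq, the adipocyte hormone adiponectin, rose by 4.09 ± 1.17 (SE), the lipid droplet genes Plin1 and Cidec by at least 3.55-fold and by 3.42 ± 0.97, and Retn, encoding resistin, by 3.11 ± 0.87. Without tacrolimus replicate 4 the differences of Adipoq, Cidec and Retn were 3.21, 2.63 and 2.59, and the bound of Plin1 was 1.76-fold. A further probe of Cidec differed by 1.02 (unadjusted p = 0.129, limma). Cfd, encoding adipsin, is on this list and on the complement list. The adipocyte marker level used as a covariate was the mean of Adipoq, Plin1, Cidec, Cfd and Retn, all members of this list. With it the mean of the adipose list was -0.28 in place of 1.74, a loss that this choice of genes largely fixed in advance. Through Cfd the complement list was also adjusted in part for its own member. Camera gave an adjusted p of 4.34e-05, and adjusted p = 0.418 with an estimated correlation. Urothelium markers were high on tacrolimus replicates 1 and 4, with scores of 1.09 and 1.96, and at -0.27 on tacrolimus replicates 2 and 3, and that list was not called (adjusted p = 0.0614).

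**Figure D2:**
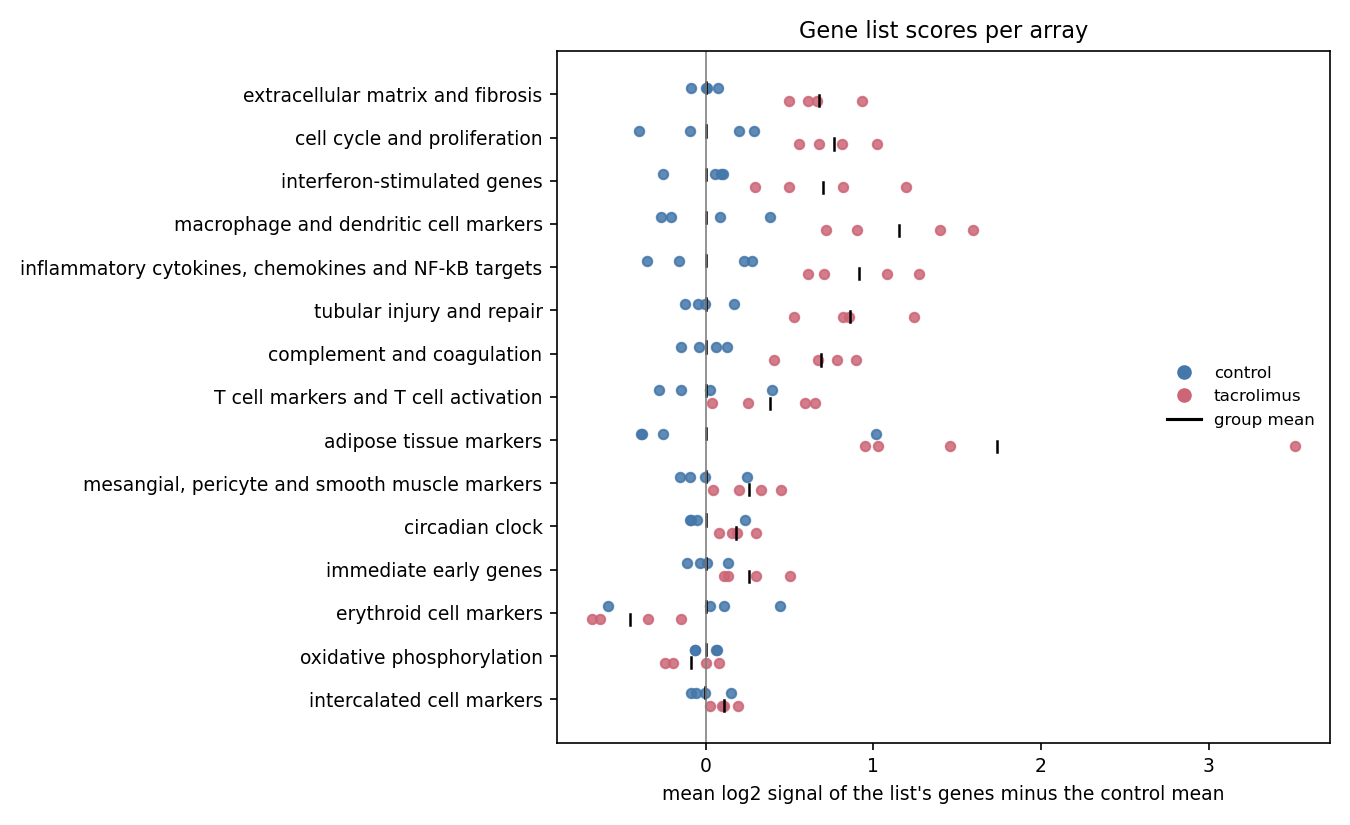
The horizontal axis gives the mean log2 signal of each list's measured genes minus the control mean, for the 15 gene lists called by camera with its preset correlation, with 1 point per array and black lines for the group means. In the 7 uppermost lists every tacrolimus array lies above every control array, and for adipose tissue markers tacrolimus replicate 4 lies at 3.51. The exact two-sided permutation p is 0.0286 for each of these 7 lists, and 0.151 adjusted over the 37 lists.

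Of the 37 lists, 15 were called by camera with its preset correlation, 13 upwards and 2 downwards, and none with an estimated correlation, where 6 were under an unadjusted p of 0.05. Fry, limma's rotation test of whether a list's genes move one way, called 6, the first 7 without the interferon list, whose adjusted p was 0.0816. The exact two-sided permutation p of the score was 0.0286 for each of the first 7, the smallest possible. Adjusted over the 37 lists it was 0.151 for each, so that none passed by that test. T cell markers had a median difference of 0.48 with no member of 30 passing adjusted over the list alone (limma) and 10 under an unadjusted p of 0.05, and Cd2, Lck and Il2rb differed by 0.87, 0.68 and 0.76 (list adjusted p = 7.34e-06, and adjusted p = 0.514 with an estimated correlation). Pdgfra, a receptor of interstitial fibroblasts, rose by 0.92 ± 0.15 (SE) as 1 of 16 mesangial, pericyte and smooth muscle markers adjusted over the list alone (list adjusted p = 0.000363, and adjusted p = 0.418 with an estimated correlation). Among 23 immediate early genes 3 rose, Egr2 by 2.33 ± 0.37, Atf3 2.21-fold and Junb by 0.89 ± 0.26, and Nr4a1 fell by 0.72 ± 0.17, adjusted over the list alone (list adjusted p = 0.00771, 0.0543 without tacrolimus replicate 2, range over settings 0.000649 to 0.0543, and adjusted p = 0.514 with an estimated correlation). No circadian clock gene of 23 passed adjusted over the list alone, with 3 higher and 1 lower at an unadjusted p under 0.05 (limma). Arntl, which encodes the clock activator BMAL1, was at a 2.14-fold lower mean, and the repressor gene Ciart differed by 1.44. Csnk1e differed by 0.38, and by 0.26 and -0.16 at its further probes, and Dbp differed by 0.72. The clock list's adjusted p (camera) was 0.00513, 0.117 with the adipocyte covariate and 0.134 without control replicate 2 and tacrolimus replicate 4. With an estimated correlation it was 0.418. No erythroid marker of 9 passed adjusted over the list alone (limma), 2 were under an unadjusted p of 0.05, and the haemoglobin chain Hbb-b2 differed by -0.87. The erythroid list's adjusted p was 0.0204, 0.0961 without control replicate 1, 0.0603 without tacrolimus replicate 2 and 0.104 without tacrolimus replicate 4, within a range over settings of 0.000143 to 0.171, and adjusted p = 0.679 with an estimated correlation. The 66 oxidative phosphorylation genes had a median difference of -0.08 and the 16 intercalated cell markers one of 0.11, with 1 member each under an unadjusted p of 0.05 and none passing adjusted over the list alone (limma). Both had an adjusted p of 0.0266. It was 0.808 and 0.514 with an estimated correlation, 0.131 and 0.0762 without control replicate 2, 0.160 and 0.0896 without control replicate 3, 0.537 and 0.191 without tacrolimus replicate 2, and for oxidative phosphorylation 0.342 without tacrolimus replicate 1, 0.960 with quantile normalization, 0.782 with normexp and quantile normalization and 0.732 in the deposited table. The ranges over settings were 5.25e-05 to 0.960 for oxidative phosphorylation and 0.00116 to 0.191 for intercalated cells.

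The other 22 lists were not called. Their median differences were 0.34 for urothelium, -0.13 for fatty acid oxidation and PPAR targets, -0.23 for heat shock proteins, -0.09 for cholesterol and fatty acid synthesis, -0.13 for the unfolded protein response, -0.14 for adrenal gland markers, -0.13 for NRF2 and oxidative stress, -0.11 for p53 targets and apoptosis, -0.07 for hypoxia and glycolysis, -0.12 for sex-dependent kidney genes, -0.10 for xenobiotic metabolism and -0.01 for skeletal muscle. Among the nephron and vessel lists they were -0.10 for the proximal tubule, -0.06 for the thick ascending limb, -0.02 for the distal convoluted tubule and the WNK-NCC pathway, 0.02 for principal cells, -0.08 for podocytes, -0.01 for endothelium, -0.07 for calcium and vitamin D handling and -0.08 for renin-angiotensin and vasoactive genes. They were -0.03 for calcineurin and FK506-binding proteins and -0.02 for B cells and plasma cells. Camera's direction was upwards although the median was negative for skeletal muscle, calcium handling, endothelium, calcineurin, the distal convoluted tubule, hypoxia, the thick ascending limb and B cells, and although the mean was negative for principal cells and the thick ascending limb.

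Of the 16 genes chosen in advance for their known relation to calcineurin inhibitors or kidney injury, 6 differed when adjusted over the list alone, and none passed over all genes (limma), with 6 under an unadjusted p of 0.05. Calb1, the calcium-binding protein calbindin of the distal nephron, was higher by 1.24 ± 0.20 (SE; adjusted p over all genes 0.0552), and a further probe by 1.31. Trpm6, the magnesium channel of the distal convoluted tubule, was higher by 1.07 ± 0.20 (adjusted p = 0.0670). The injury marker Lcn2 was higher by 1.17 ± 0.25, the collagen gene Col1a1 by 1.31 ± 0.28 and Spp1, encoding osteopontin, by 0.90 ± 0.22 (adjusted p = 0.0948, 0.0948 and 0.121). In these 5 genes all 4 tacrolimus arrays lay above all 4 control arrays, which gives an exact two-sided permutation p of 0.0286, the smallest the 70 assignments allow, and 0.0915 after Benjamini-Hochberg adjustment over the 16 genes. Ren1, encoding renin, was lower, at 2.10 ± 0.58 against 3.25 ± 0.69 in controls (SD, n = 4 per group), a difference of -1.16 (adjusted p over all genes 0.228, exact permutation p = 0.114). The sodium-chloride cotransporter gene Slc12a3 differed by 0.34 ± 0.16 (SE) and the klotho gene Kl by -0.20 ± 0.12. Havcr1, encoding the injury marker KIM-1, differed by -0.25 ± 0.20, and its further probe by -0.79 (unadjusted p = 0.00881, limma). Agt differed by 0.01 ± 0.34, Trpv5 by -0.08 ± 0.19, Tgfb1 by 0.01 ± 0.20, Rcan1, a target of calcineurin signalling, by -0.08 ± 0.13, and Nfatc1 by -0.06 ± 0.36. The drug's binding protein gene Fkbp1a differed by -0.11 ± 0.12 and the calcineurin subunit gene Ppp3ca by -0.03 ± 0.10. The signs of Agt, Trpv5, Tgfb1, Nfatc1, Fkbp1a, Ppp3ca and Havcr1 changed under some of the other settings, and for Havcr1 the difference ranged from -0.52 to 0.05. Calb1 passed over all genes under 7 other settings, among them the deposited value table (adjusted p = 0.0425), within a range over all settings of 0.0255 to 0.478, and Trpm6 passed under normexp with the 75th percentile (0.0311), the deposited table (0.0480) and an intensity trend (0.0405), within a range of 0.0311 to 0.571. Col1a1 passed with array weights only (0.0452, range 0.0452 to 0.522). Ren1 and Lcn2 passed only with the replicate number as a block (0.0446, range 0.0446 to 0.601, and 0.0493, range 0.0493 to 0.573).

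**Figure D3:**
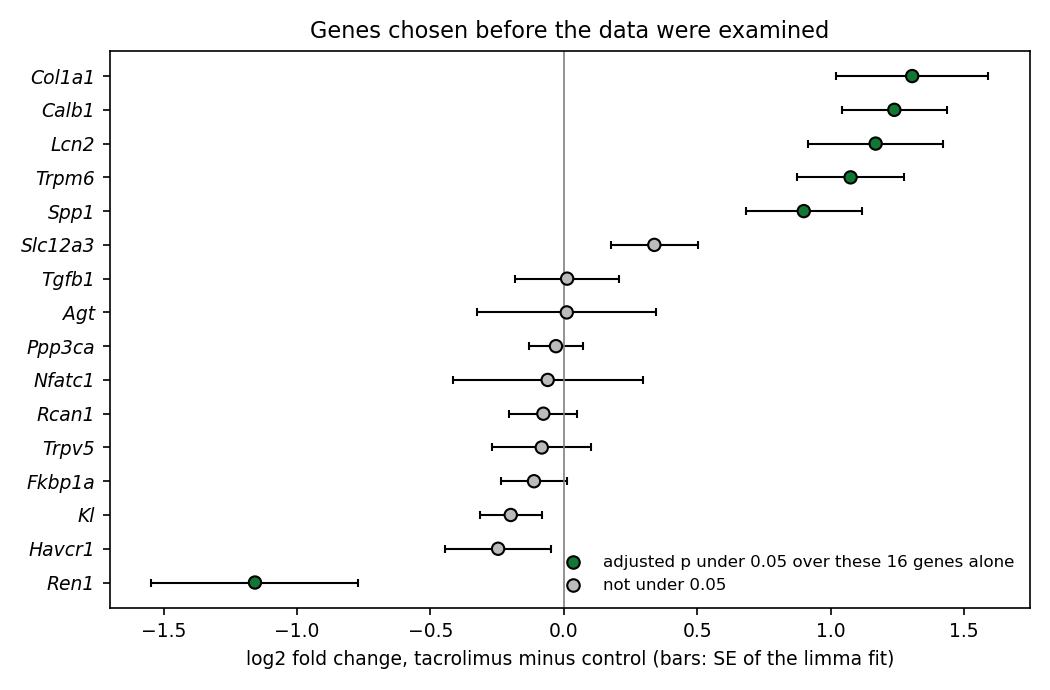
The horizontal axis gives the log2 fold change, tacrolimus minus control, of the 16 genes chosen in advance, with bars for the standard error of the limma fit. Green points mark the 6 genes with an adjusted p under 0.05 over these genes alone, from Ren1 at -1.16 to Col1a1 at 1.31.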

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

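The comparison of macrophage with B cell markers and that of the spike-in probes before normalization, with its limit, were chosen after the values they use were seen, and the other tests of explanations were written down before their results were computed. Within the groups of 4, 248 sets of values were searched for an array far from the other 3, for the genes named and the list scores. This marked 18, where chance marks about 12.4.

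For the adipose list, control replicate 2 lay at 1.02 with the next array at -0.26. Its Cidec level was -3.04 against -6.08 in the next control array, and Plin1 on tacrolimus replicate 4 was -1.44 against -5.14. Control replicate 1 was apart for Clic6 (-7.10, next -8.12), H2-DMb2 (-6.87, next -8.01), Nfatc1 (0.83, next -0.63) and the circadian list (0.24, next -0.05). Control replicate 3 was low for Junb (-5.42, next -4.36), the B cell list (-0.39, next 0.11) and the interferon list (-0.25, next 0.05). Control replicate 4 was apart for Ndufb6 (5.91, next 6.05) and the thick ascending limb list (0.33, next -0.10), and control replicate 2 for Bpgm (2.03, next 1.83). Among the tacrolimus arrays, Ren1 was lowest on replicate 1 (1.23, next 2.31), C3 and Krt20 were highest on replicate 2 (5.94, next 4.65, and 0.73, next -0.60), and Oas1a and Tbc1d20 were lowest on replicate 4 (1.01, next 1.55, and 0.64, next 0.83).

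Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, called as many as 57 genes, and the highest of the others called 1. Chance assignment of the arrays is argued against for this count, at the smallest share that 35 splits allow, and is not excluded. For the number of gene lists called by camera with its preset correlation, 10 of the 35 splits, the real one included, gave at least 15, and the highest of the others gave 21. Chance is therefore not excluded for the number of lists.

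For the joint rise of the 7 leading lists, fat carried over with the kidney as the whole cause is argued against only by the sizes of the shifts. With the adipocyte marker level of each array in the model, their median was 0.76 against 0.77 without it. The score differences ran from 0.59 ± 0.20 (SE) to 1.15 ± 0.44. That of the extracellular matrix was 0.72 ± 0.17. Errors were wide for the cell cycle (0.742 ± 0.321), interferon (0.844 ± 0.366) and inflammatory (0.895 ± 0.379) lists, so that fat is not settled for every list. By camera with its preset correlation 7 of the 7 lists were still called higher. Such calls were also frequent in other splits of the arrays, so that they do not decide. The same model called 0 single genes (smallest adjusted p 0.0543, limma), where the 57 differences kept their median size (1.54 against 1.45) at a larger median SE (0.28 against 0.18). With an estimated correlation none of the 7 lists was called even without the covariate (camera, adjusted p from 0.123 to 0.294). The marker level lay between -2.97 and 0.74 on the control arrays and between 0.66 and 4.36 on the tacrolimus arrays. The model therefore separates fat from treatment poorly, and a part played by fat stays open. Lymphoid tissue or blood would bring B cell markers. On 4 of the 4 tacrolimus arrays the macrophage score exceeded the B cell score by more (0.72 to 1.90) than on any control array (at most 0.24). The macrophage list was taken for its rise, so that only the B cell score informs here, from -0.298 to 0.338 (controls -0.391 to 0.149). T cell scores ran from 0.041 to 0.651 (controls -0.280 to 0.398) and erythroid scores from -0.675 to -0.147 (controls -0.581 to 0.447). These scores do not decide, and a part played by lymphoid tissue or blood stays open. For a general shift of signal with the slide row, the spike-in probes do not decide. Before normalization the median of their differences over 8 levels was -0.136. The SE between arrays, taken from each array's mean over these levels, was 0.0725. With 2 SE added, the size was short of a limit of 0.5 chosen after the values were seen. It was not within the stricter 0.2 set at first by more than the SE. The lists were measured relative to a percentile of each array, which takes out a general shift. No conclusion on the rise of the lists is therefore drawn from the spike-in probes. An effect of the row on particular probes cannot be told apart from the treatment, as each group filled 1 row, and the treatment itself stays open and untested by these comparisons.

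Genes raised from background, such as Snph and Clic6, were set against 2 explanations. A higher signal floor on the tacrolimus arrays is argued against: the 16093 probes not well above background on any control array differed by a median of -0.00755 (quartiles -0.16 and 0.26). An artefact of single probes cannot be told apart for these genes: of the 15 other probes of all genes called higher, 33.3% moved the same way at an unadjusted p under 0.05, and 5 of the 8 that were well above background on at least 4 arrays, while of the genes raised from background only Cnr1 had another probe, which was dim on every array. A response to the treatment stays open for these genes.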

How the results depend on the processing

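The adipocyte marker covariate was chosen after seeing the data. So was the leaving out of control replicate 2 and tacrolimus replicate 4, each the highest of its own group in these markers. Under all alternatives that tested them, the 57 called genes had the same direction of difference. Counts of called genes (higher and lower), of the 17 named genes still called and of the 16 advance genes called moved by over 1.5 times as follows, and the cause was not tested unless stated. Normexp with the 75th percentile called 285 genes (225 and 60) and 2 advance genes, normexp with quantile normalization 131 (90 and 41), 11 named and 1 advance gene, and the values as deposited gave 180 genes (137 and 43) and 2 advance genes. With no filter, 34748 genes were tested and 32 called (27 and 5), 9 of them named. With the filter on all 8 arrays, 151 were called (108 and 43), 7 named and 1 advance gene; the other named genes were not tested. The mean of a gene's probes called 1 advance gene. Trend and robust estimation called 221 (157 and 64) and 2 advance genes, and array weights 309 (221 and 88) and 2 advance genes. Leaving out 1 array left 7 to 56 genes called (7 to 49 and 0 to 7), 3 to 13 named genes, no advance gene and 12 to 18 lists, with fewer arrays. The replicate number as a block called 103 genes (93 higher), of which 28 were among the 57, with 9 named genes, 2 advance genes (Ren1 and Lcn2) and 16 lists. The numbers were not taken as pairs because the labels do not say that a number marks a shared litter, cage or day. Deviations of same-numbered arrays correlated by 0.02 to 0.16 and others by -0.15 to 0.06. Of the 8 arrays 7 were closest, in the other group, to the array with their own number, which is also their column on the slide. An effect shared by arrays of the same number or column is therefore not excluded. With the adipocyte marker covariate 0 genes were called (0 higher, 0 lower, 0 of the named), 2186 at an unadjusted p under 0.05, with a smallest adjusted p of 0.0543. The median size of the 57 differences was 1.54 against 1.45 without it, and their median SE 0.28 against 0.18, so that the calls ended with the larger error. The marker level lay between -2.97 and 0.74 on the control arrays and between 0.66 and 4.36 on the tacrolimus arrays. This model therefore separates the marker level from the treatment poorly. The mean of the adipose list turned from 1.74 to -0.28 (adjusted p = 0.846, camera), where members of that list made up the covariate. Without control replicate 2 and tacrolimus replicate 4 together 8 genes were called (8 and 0), 3 of them named. Tacrolimus replicates 1 and 3, at marker levels of 1.60 and 0.84 against 0.74 on control replicate 2, stayed in that fit. Across settings other than fry and the estimated correlation, the 7 leading lists stayed called higher (highest adjusted p 1.33e-05). The estimated correlation called 0 lists, 6 at an unadjusted p under 0.05, and fry 6. Dim probes limit the folds: Snph differed by 1.74 and 1.77 with normexp, which adds an offset, and by 2.53 in the deposited table, where no background is subtracted, against 5.15 in the values above.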

Other observations

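The genes in this part were chosen after their values were seen. Gc, the vitamin D-binding protein, rose by 1.62 ± 0.14 (SE) and the iron carrier transferrin, Trf, by 0.95 ± 0.13, and a further probe of each moved the same way, by 1.58 and 0.98. Bak1, an effector of mitochondrial apoptosis, rose by 0.82 ± 0.09 while the p53 and apoptosis list was not called.

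In the calcium and vitamin D list, Cyp27b1, the enzyme that makes active vitamin D, had a 2.30-fold higher mean and the calcium-binding protein gene S100g differed by 0.68 ± 0.20 (SE), neither passing adjusted over the list alone.

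Id1, Id3 and Atoh8, targets of BMP-SMAD signalling, rose by 1.76 ± 0.15, 1.44 ± 0.14 and 0.87 ± 0.13 (SE; adjusted p = 0.00743, 0.0111 and 0.0470, limma). Tacrolimus binds FKBP12, which also binds type I BMP receptors, and a hypothesis is that BMP-SMAD targets as a group may be higher in these kidneys. Of 12 other targets written down before the test 11 were measured: 8 were higher, the median difference was 0.18 and camera gave an unadjusted p of 0.0201 upwards, and 0.0506 with an estimated correlation. Smad9 differed by 1.66, Id4 by 0.81, Id2 by 0.42 and Smad7 by 0.36, while Nog differed by -0.87 and Msx1 by -0.26. None of the 11 passed over all genes. Without Smad9 the camera p was 0.118, without Id2 0.0780, without Smad7 0.0812 and without Id4 0.0564, while it was 0.00357 without Msx1, 0.00469 without Msx2 and 0.00688 without Nog, and from 0.0195 to 0.0330 without each of the other 4.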
